A study of Mus musculus with 33 samples.

How the data were processed

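RNA of sorted mouse cells was measured in 33 libraries. Per the labels' protocols, thymi were digested with Liberase TH and DNase, the skin cells called HFC were released with trypsin, RNA of the sorted cells was taken up on Dynabeads, and 3'-end libraries were made by MARS-seq. The submitters' processing notes name bcl2fastq, cutadapt, STAR 2.4.2a, HTSeq, DESeq2 and the mouse build mm10, without the role or order of each. The settings of these steps are not given in the sources used here.

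The deposited table holds normalized signal values for 15273 genes by symbol, with each library's values summing to 100, so a value is the share of a library's UMIs in percent. The notes do not state how the authors scaled them. The low values of each library were whole multiples of 1 step, and dividing by that step gave whole UMIs in 33 of 33 libraries (within 0.01), with totals from 98670 to 1732688. The library totals set the precision: a gene with no UMI in a library can still hold up to 3 UMIs of the total. These floors cover counting error only. Mitochondrially encoded genes are 0 of the 15273, so no mitochondrial share was computed. No column was left without a sample.

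The analysis plan had assumed normalized UMIs. As the values are percentages, they were multiplied by 1 constant, to the median library total of 570253 UMIs, before log2(value + 1) was taken, and the same test was used. A planned rescaling to the same total would have changed nothing and was not run. Fold changes are on this log2 scale, which understates changes of genes with few UMIs. Levels are printed as CPM, UMIs per 1000000, from the same shares.

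Groups follow the sample titles. Genes with 5 or more normalized UMIs in at least 2 of the libraries of a fit were tested with limma 3.58.1 (linear model, moderated test with an intensity trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p below 0.05 as the threshold, without a minimum fold. The comparisons were each 6-week population against the others, HFC against 6-week TEC, E17 against E15, each day 6 population against the other 2, 6 weeks against day 6 within mTEC1, mTEC2 and mTEC4, their interaction, and 6-week cTEC against embryonic TEC. Embryonic and day 6 libraries were fitted together to share 1 estimate of the spread. Foxn1 was also compared by exact permutation tests of mean log2 levels, two-sided, adjusted over 3 tests.

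For 28 gene lists of cell types and pathways, drawn from textbook markers before the data were examined, members passing over all genes and members passing when adjusted over the list alone were counted. Each list was tested against the other genes with limma's camera at a preset correlation of 0.01, again with the correlation estimated, and with fry beside it. Of 305 listed genes 266 were in the table. The B cell, erythroid and melanocyte lists had fewer than 3 tested members and were not tested. The tests of the others are adjusted over the 25 lists of a comparison. Some genes belong to several lists, such as Cd74 to the Aire-stage and MHC class II lists, so lists are not independent.

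The genes named were set by a rule written together with these lists: Foxn1, Psmb11, Prss16, Ccl21a, Aire, Krt10 and Dclk1 in each comparison, the 10 most raised and 10 most lowered called genes whose libraries do not overlap (5 and 5 where a group has 2 libraries), and up to 4 members of each described list with the smallest adjusted p. Predicted genes and pseudogenes were left out of the second part. A few genes that meet this rule are not reported here. The 6-week marker values per library, Gapdh and the structure of the 6-week libraries were chosen after the data were seen. Coordinates are from GENCODE M21 on GRCm38, in which 14991 of the symbols were found.

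Alternatives comprised pseudocounts of 0.5 and 5, no filter, a filter at a mean of 10, median of ratios scaling, robust moderation, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 on the recovered UMIs, a block on the number in the titles, and leaving out each library. Fits of the compared groups alone and of the 6-week TEC libraries as 1 group were added after the data were seen. Each fit was tested on simulated data with 100 genes changed 2-fold and 100 changed 8-fold. Of the 8-fold genes it recovered 51 for HFC, 64 for E17 against E15, 83, 77 and 83 for the day 6 labels mTEC1, mTEC2 and mTEC4, 19, 37 and 36 for the age comparisons of these labels, 0 for the interaction and 58 for 6-week cTEC against embryonic TEC, and of the 2-fold genes at most 10 in any fit. Unchanged genes were called too: 3 for HFC, 1 for E17 against E15, and 8, 17 and 10 for the day 6 labels in that order. These false calls were 1, 4 and 6 for age, 0 for the interaction, 1 for cTEC against embryonic TEC and 3 to 7 for the 6-week labels. Other calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.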

Results

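Gene expression was measured in 33 libraries of sorted mouse cells by bulk MARS-seq, which sequences the 3' ends of transcripts and counts molecules through unique molecular identifiers (UMIs). All mice were C57BL/6. The thymic epithelial cells (TEC), the stromal cells that direct T cell development, came from wild-type mice at 4 ages. There were 2 libraries of TEC at embryonic day 15 (E15) and 2 at embryonic day 17 (E17). Postnatal day 6 gave 2 libraries each of populations labelled mTEC1, mTEC2 and mTEC4. At 6 weeks there were 4 each labelled cTEC, mTEC1, mTEC2, mTEC3 and mTEC4. In this field cTEC stands for cortical and mTEC for medullary TEC. A further 3 libraries held cells that the labels call HFC, sorted from the dorsal skin of 4-week-old mice as positive for an EGFP reporter of Foxn1. The library totals ran from 1007370 to 1732688 UMIs in embryonic TEC, from 287189 to 638343 at day 6, from 98670 to 1369629 at 6 weeks and from 520844 to 679168 in HFC. Between 8828 and 14854 of 15273 genes were detected per library. Libraries of 1 group differed from each other beyond counting noise, with a chi-square per degree of freedom between 2.82 and 36.1. The labels do not say whether libraries of a group came from separate animals, so every p-value measures only the spread between these samples, which may be technical. Levels are given in CPM, UMIs per 1000000 UMIs of the library, as mean ± SD.

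The series is concerned with how Foxn1, the transcription factor that TEC need to differentiate and hair follicle cells need to form a coat, is itself regulated. Foxn1 (chromosome 11, 78357577 to 78386558, minus strand, GRCm38) was most abundant in embryonic TEC, at 810 ± 221 CPM over the 4 E15 and E17 libraries. It stood at 425 ± 13.0 in the libraries labelled day 6 mTEC1, at 300 ± 68.4 in those labelled day 6 mTEC4 and at 68.5 ± 29.3 in those labelled day 6 mTEC2 (n = 2 each). At 6 weeks the 20 TEC libraries held 126 ± 92.9, and the 3 HFC libraries 24.9 ± 12.7. The libraries labelled 6-week cTEC (118 ± 137, n = 4) lay 3.56 log2 units below embryonic TEC, with an exact permutation p of 0.0286, the smallest that 70 assignments allow, and an adjusted p of 0.0857 over 3 tests. The difference was -4.31 without cTEC 191 and -2.92 without cTEC 196. Against the 16 libraries labelled mTEC (128 ± 84.6) they differed by -0.38 log2 units (exact permutation p = 0.675), a difference of -1.13 without cTEC 191 and 0.26 without cTEC 196. The cTEC marker list was the highest population list in 0 of the 4 libraries labelled cTEC. Both results are therefore differences between labels, and Foxn1 in cortical against medullary TEC was not tested. HFC differed from the 20 TEC libraries at 6 weeks by -1.76 log2 units (exact permutation p = 0.0740, adjusted p = 0.111). None of these 3 two-sided tests passed the adjustment. A comparison added after the data were seen set embryonic TEC against all 20 libraries at 6 weeks and gave a difference of 3.25 log2 units (permutation p = 0.00104 over all 10626 assignments).

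**Figure D1:**
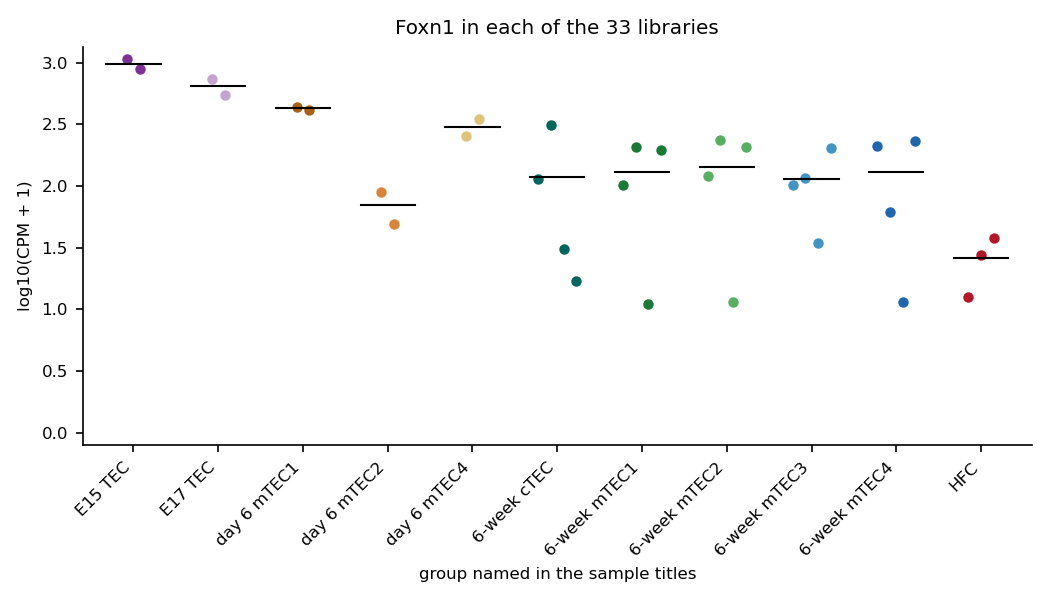
Foxn1 in each of the 33 libraries as log10(CPM + 1), by the group in the sample titles; points are libraries and bars are group mean CPM on that axis. The 4 embryonic libraries lie between 547 and 1065 CPM, above each of the 6-week libraries, whose highest is 313.

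HFC differed from 6-week TEC in keratins, hair follicle regulators and antigen presentation genes. Krt14 and Krt5, the keratin pair of basal keratinocytes, reached 33530 ± 3556 and 25010 ± 3246 CPM in HFC against 803 ± 813 and 1229 ± 1280 in TEC. Krt17 rose by 4.04 log2 units and Krt6a by 9.17, to 12280 ± 1481 from 37.9 ± 44.6. Krt8 and Krt18, the keratin pair of simple epithelia, went the other way: Krt8 stood at 5.09 ± 5.80 in HFC (n = 3) against 2448 ± 1222 in TEC (n = 20), a log2 change of -8.65 ± 0.45 (SE). Among 12 tested hair follicle transcription factors, 5 rose and 2 fell, the same numbers when adjusted over the list alone. Hoxc13, a regulator of hair keratins, was at 135 ± 33.2 in HFC and 0.0365 ± 0.163 in TEC, Lhx2, a hair follicle stem cell factor, rose by 6.16 and Tbx1 by 5.70 log2 units. The list of hair follicle stem cell and outer root sheath genes had 6 of 10 members higher and 1 lower (7 and 1 adjusted over the list alone), with Krt15 up by 4.52 log2 units. These 2 lists also passed with an estimated correlation between members, at adjusted p = 0.0110 and adjusted p = 0.000953. Of 14 hair shaft and inner root sheath genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), among them the inner root sheath keratins Krt27 (5.66), Krt71 (5.60) and Krt25 (5.21), with adjusted p = 0.297 with an estimated correlation. Of 15 genes of cornified keratinocytes 4 rose and none fell (9 adjusted over the list alone; adjusted p = 0.310 with an estimated correlation), including Krt10 (chromosome 11, 99385254 to 99389364, minus strand) at 2420 ± 1146 against 484 ± 577 (log2 3.19 ± 1.03, adjusted p = 0.0291).

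Genes of antigen presentation and of TEC identity were lower in HFC. Of 11 tested MHC class II presentation genes 10 fell and 0 rose (11 adjusted over the list alone). Cd74, the invariant chain, stood at 16.5 ± 6.14 CPM against 8597 ± 5614, and H2-Eb1 (log2 -8.41) and H2-Aa (-8.21) fell likewise. The Aire-stage mTEC list had 14 of 16 members lower and 0 higher (15 adjusted over the list alone). Aire (chromosome 10, 78030022 to 78043610, minus strand), which drives display of self-antigens in the medulla, stood at 2.51 ± 2.27 against 514 ± 903 (log2 -4.74 ± 1.60, adjusted p = 0.0368). Of 13 cTEC genes 8 fell and of 9 Foxn1 targets in TEC 7 fell, with 0 higher in both and the same numbers adjusted over each list alone; Prss16, a thymus-specific protease, fell by 5.88 log2 units. Microfold cell genes fell in 6 of 8 (7 adjusted over the list alone) and NF-kB receptors and subunits in 8 of 12 (10 adjusted over the list alone). These lists passed camera's preset correlation and lost the call with an estimated one, at adjusted p = 0.106 for MHC class II, adjusted p = 0.202 for the Aire stage, adjusted p = 0.542 for cTEC, adjusted p = 0.455 for Foxn1 targets and adjusted p = 0.297 for both others. The developmental regulators Pax9 and Pax1 had no UMI in any HFC library, which allows up to 1.63 CPM, so they were at least 34.5-fold and 138-fold lower than in TEC. Cxcl10, an interferon-induced chemokine, had none either and was at least 398-fold lower. Psmb11, the thymoproteasome subunit of cTEC (chromosome 14, 54621433 to 54629556, plus strand), had no UMI in HFC and 39.2 ± 78.6 CPM in TEC (adjusted p = 0.297). Foxn1 (adjusted p = 0.185) and the tuft cell kinase Dclk1 (log2 -1.83, adjusted p = 0.124) did not pass either. Mixed or smaller calls were found in the other lists. The Ccl21a and Pdpn mTEC list, placed up by camera, had 4 of 11 higher and 3 lower, the same numbers adjusted over the list alone (adjusted p = 0.455 with an estimated correlation). Its median of -0.55 and mean of 0.49 differ in sign, and Ccl21a itself was not analysed here. Thymocyte genes, markers of a cell type that TEC sorts can carry over, fell in 5 of 13 (10 adjusted over the list alone; adjusted p = 0.542 with an estimated correlation). Cell cycle genes were placed up with 0 of 12 members called, and 0 adjusted over the list alone (adjusted p = 0.542 with an estimated correlation). Camera placed none of the other 12 lists apart. Among these, 4 of 8 organogenesis factors, 6 of 14 Notch and Wnt genes and 3 of 8 endothelial genes fell, and 1, 3 and 0 rose.

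**Figure D2:**
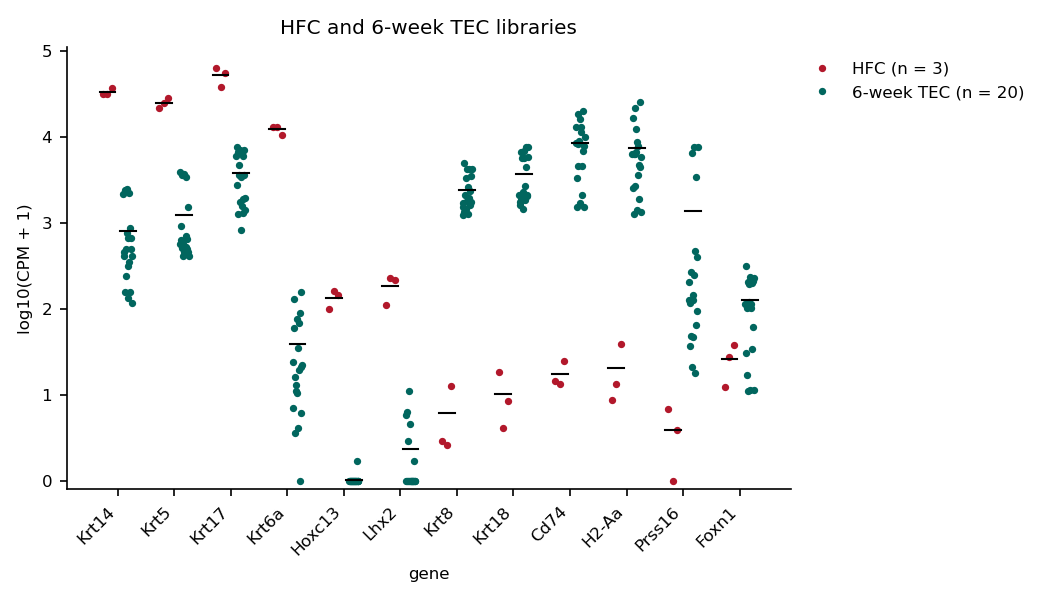
Levels of 12 genes as log10(CPM + 1) in the 3 HFC libraries and the 20 TEC libraries at 6 weeks; points are libraries and bars are mean CPM on that axis. Krt14 averages 33530 in HFC and 803 in TEC, while Cd74 averages 16.5 and 8597.

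By limma on 13743 genes, 569 genes were higher and 2317 lower in HFC. The median log2 change over all tested genes was -0.78, and the printed changes are not re-centred on it. With median of ratios scaling it was -0.44, with 1088 genes higher and 1526 lower. On the recovered UMIs edgeR called 1391 higher and 1453 lower and DESeq2 1331 and 2659, so the size of the excess of lower genes differed between settings. With the 20 TEC libraries taken as 1 group, a comparison added after the data were seen, 634 genes were higher and 2640 lower, 2878 of them shared. The count fell to 1547, 1800 and 1626 without HFC library 1, 2 or 3. Aire and Krt10 lost their calls in each of these 3 fits and Prss16 without library 2, and Aire also lost it by edgeR and with median of ratios scaling. HFC and TEC also differed in age, tissue and dissociation.

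Between E15 and E17, stress response genes and part of the Aire-stage list rose. Aire went from 40.4 ± 7.39 to 372 ± 15.3 CPM (log2 3.16 ± 0.45, adjusted p = 0.0127, n = 2 and 2), and Fezf2, the other transcription factor that directs self-antigen expression in mTEC, rose by 3.64 log2 units. The Aire-stage list had 4 of 15 members higher and 0 lower (12 adjusted over the list alone; adjusted p = 0.0918 with an estimated correlation), including Cd52 (3.23) and Hdc (4.14). Ctss, a cathepsin that processes antigen, and H2-Oa were the 2 of 10 MHC class II presentation genes that rose (8 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation). All 12 dissociation stress genes were higher when adjusted over the list alone and 8 of them over all genes. Fos stood at 470 ± 56.1 against 57.5 ± 39.4, with Nr4a1 (3.29), Atf3 (3.32) and Hspa1a (2.33) also up, and this list kept its call with an estimated correlation (adjusted p = 0.0159).

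The genes with the largest rises were Clca3b (5.51 log2 units), Saa3 (4.92), Laptm5 (192 ± 2.82 against 6.14 ± 3.78) and Vmo1 (4.54), and Serpinb12, with no UMI at E15, was at least 35.4-fold higher. The claudins Cldn7 (2.94) and Cldn3 (2.66), the keratinocyte gene Ly6d (2.72), the myeloid marker Lyz2 (3.0) and the microfold cell factor Spib (1.89) rose as well. Only 2 genes fell: the imprinted transcript H19, at 117 ± 30.8 against 356 ± 38.8, and Gapdh, a glycolytic enzyme, at 23.1 ± 3.87 against 730 ± 27.7. Gapdh fell into separate ranges across the whole series, also within HFC, so its fall is not read as a change with embryonic age. Foxn1 (642 ± 134 against 978 ± 122), Psmb11 (log2 -0.33), Prss16 (0.13), Krt10 (-0.19) and Dclk1 (-0.11) did not pass. Camera also placed up the lists of muscle, tissue-restricted antigens, mesenchyme, myeloid cells and NF-kB receptors and subunits, and cell cycle genes down. Lyz2 was the 1 gene of these 6 lists called over all genes, and adjusted over the list alone 4 of 8 muscle genes and at most 2 members of any other passed. With an estimated correlation none held, from adjusted p = 0.0918 for muscle to adjusted p = 0.337 for tissue-restricted antigens and for NF-kB. Of 11543 genes, limma called 86 higher and 2 lower at E17, fitted together with the day 6 libraries. In a fit of the 4 embryonic libraries alone, added after the data were seen, 452 were higher and 53 lower, with all 88 shared, edgeR called 167 and DESeq2 247. Leaving out E15 library 1 or 2 left 13 or 16 calls, and leaving out E17 library 1 or 2 left 5 in both cases. Of the 22 called genes named here, Laptm5 and Gapdh kept the call without each of the 4 libraries, Fezf2 and Fos only without those of E15, and the other 18 lost it in each case.

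At day 6 the 3 labelled populations differed from each other. The libraries are named here by their titles, and whether these fit the cells was not checked by another measurement. The gene lists used here assign the Aire stage to mTEC2 and tuft genes to mTEC4. Aire was highest in the libraries labelled mTEC1, and the tuft gene Trpm5 in those labelled mTEC2 (478 ± 37.7 CPM). These markers go against the titles, so the differences below are those of labels and not traits of the numbered populations. The libraries labelled day 6 mTEC1 had higher cortical, Aire-stage and antigen presentation genes and lower endothelial genes than those labelled mTEC2 and mTEC4. Aire was at 495 ± 86.2 CPM (n = 2) against 46.6 ± 32.8 (n = 4), Foxn1 at 425 ± 13.0 against 184 ± 140 (log2 1.59 ± 0.28, adjusted p = 0.0167), and Psmb11 at 209 ± 23.7 against 74.0 ± 63.4. All 9 Foxn1 targets rose (9 adjusted over the list alone; adjusted p = 0.0860 with an estimated correlation), as did 9 of 13 cTEC genes (11; adjusted p = 0.0860), such as Prss16 (2.36), Tbata (2.27) and the chemokine Cxcl12 (1.54). The Aire-stage list had 8 of 15 higher (12 adjusted over the list alone; adjusted p = 0.0920 with an estimated correlation), with Fezf2 up by 2.67. MHC class II presentation genes rose in 7 of 10 (9 adjusted over the list alone; adjusted p = 0.10 with an estimated correlation), with Cd74 at 10950 ± 2839 against 3038 ± 1152. Tissue-restricted antigen genes rose in 3 of 11 (10 adjusted over the list alone; adjusted p = 0.0920 with an estimated correlation), and Gip, an incretin hormone with no UMI in the other day 6 libraries, was at least 26.7-fold higher. Fabp6, a bile acid binding protein, rose by 5.68 and Ang4, a Paneth cell peptide, by 5.18 log2 units. Endothelial markers fell in 7 of 8 (8 adjusted over the list alone; adjusted p = 0.0860 with an estimated correlation), with Kdr at 3.51 ± 4.96 against 105 ± 53.6. Plvap (log2 -3.96), Emcn (-4.19) and Cdh5 (-3.80) fell with it, as did Gpihbp1, a capillary protein, at 18.2 ± 21.3 against 1040 ± 495.

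Other lists held fewer calls in the libraries labelled day 6 mTEC1. Tuft genes fell in 2 of 18 (8 adjusted over the list alone) and muscle genes in 1 of 8 (4 adjusted over the list alone), both at adjusted p = 0.0860 with an estimated correlation. The other side of this comparison includes the libraries labelled mTEC2, which were high in both lists. NF-kB receptors and subunits rose in 1 of 12 (7 adjusted over the list alone; adjusted p = 0.0920 with an estimated correlation) and organogenesis factors in 2 of 8 (2; adjusted p = 0.472). Camera also placed down microfold, dissociation stress and mesenchymal genes with 0 members called over all genes and 2, 1 and 0 adjusted over the list alone, at adjusted p = 0.424, adjusted p = 0.239 and adjusted p = 0.302 with an estimated correlation. Krt8 (1.26) and Krt17 (1.86) rose, and Krt10 (log2 -0.55) and Dclk1 (-0.84) did not pass. In all, limma called 233 genes higher and 128 lower, and a fit of the 6 day 6 libraries alone, added after the data were seen, called 24. By limma 0 genes were called without library 1 or without library 2 labelled day 6 mTEC1, and 1745 and 579 without library 1 or 2 labelled day 6 mTEC2. Prss16 and Kdr lost their calls without either library labelled day 6 mTEC4. With all libraries edgeR called 451 and DESeq2 505, and 1884 genes had an unadjusted p below 0.05.

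The libraries labelled day 6 mTEC2 had higher tuft and muscle genes and lower cortical ones than the other day 6 libraries. Tuft cell genes, which belong to a chemosensory epithelial type, rose in 13 of 18 with 0 lower (15 adjusted over the list alone). Avil stood at 1202 ± 124 against 14.9 ± 18.2 CPM, Sh2d6 at 759 ± 211 against 4.36 ± 3.71, and the taste channel Trpm5 (chromosome 7, 143069153 to 143094642, minus strand) at 478 ± 37.7 against 10.3 ± 13.4. All 8 muscle genes rose (8 adjusted over the list alone), including skeletal actin Acta1 (7.03 log2 units), Myl1 (6.12) and the myogenic factor Myog (4.92). Both lists passed with an estimated correlation, each at adjusted p = 0.0437. Foxn1 was at 68.5 ± 29.3 against 362 ± 82.6 (log2 -2.41 ± 0.28, adjusted p = 0.00108). Cortical genes fell in 10 of 13 (12 adjusted over the list alone) and Foxn1 targets in 8 of 9 (9), both at adjusted p = 0.111 with an estimated correlation, such as Psmb11 (log2 -2.72), Prss16 (-2.97), Ly75 (-2.74) and Cxcl12 (-2.44). Il7, the cytokine that thymocytes need, had no UMI and was at least 17.0-fold lower.

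MHC class II presentation genes fell in 7 of 10 in the same libraries (9 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation), among them H2-DMa (log2 -1.83) and H2-Aa (-1.67). Aire-stage genes fell in 5 of 15 (9 adjusted over the list alone; adjusted p = 0.257 with an estimated correlation), while Aire itself (64.1 ± 44.2 against 262 ± 274, adjusted p = 0.119) did not pass. Ciliated cell genes rose in 3 of 5 (5 adjusted over the list alone; adjusted p = 0.205 with an estimated correlation) and endothelial genes in 1 of 8 (5; adjusted p = 0.363). Organogenesis factors (1 higher and 3 lower of 8), NF-kB receptors and subunits (2 lower of 12) and tissue-restricted antigens (0 of 11) were placed down by camera. Adjusted over the list alone these counts were 1 and 4, 4 and 0, and with an estimated correlation the lists were at adjusted p = 0.40, adjusted p = 0.205 and adjusted p = 0.394. Krt19 (3.34), Spib (2.11) and the mucin Muc5b (6.50) rose, the hormone precursor Pomc fell by 4.68 log2 units, and Krt10 (-0.11) and Dclk1 (1.10) did not pass. Krt10 was called higher (1.39, adjusted p = 0.0178) without library 1 labelled day 6 mTEC2. With 501 genes higher and 404 lower this was the comparison with the most calls at day 6, and the day 6 libraries alone gave 163. There were 552 and 487 calls without library 1 or 2 labelled day 6 mTEC1 and 2687 without library 1 labelled day 6 mTEC2. Sh2d6 and Muc5b fell below the filter on low values without either library labelled day 6 mTEC2 and were not tested there.

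**Figure D3:**
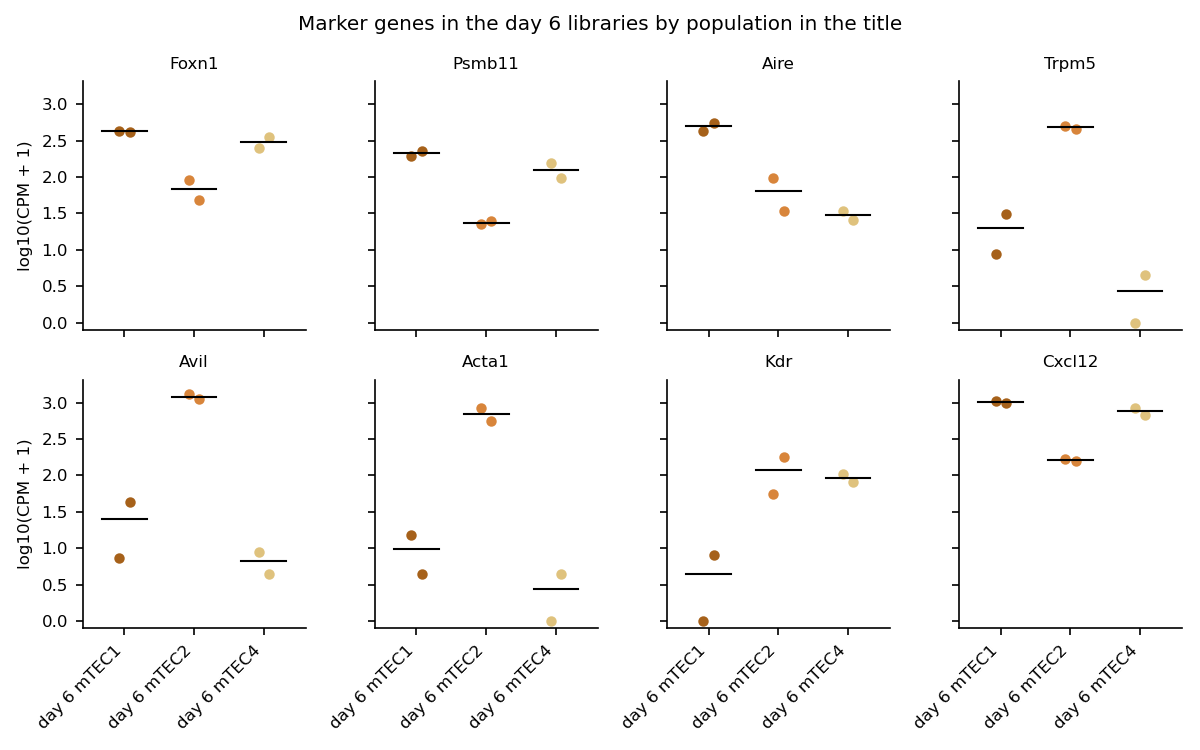
Levels of 8 genes as log10(CPM + 1) in the 6 day 6 libraries, by the population in their titles; points are libraries and bars are mean CPM on that axis. Aire averages 495 in the libraries labelled mTEC1, Trpm5 478 in those labelled mTEC2, and Kdr 3.51 in those labelled mTEC1.

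The libraries labelled day 6 mTEC4 were low in genes of the tuft, muscle and pan-epithelial lists and in Aire. Tuft genes fell in 7 of 18 with 0 higher (12 adjusted over the list alone; adjusted p = 0.199 with an estimated correlation), with Trpm5 at 1.74 ± 2.46 against 248 ± 266 CPM and Sh2d6 at a log2 change of -4.90. Muscle genes fell in 4 of 8 (8 adjusted over the list alone; adjusted p = 0.106 with an estimated correlation) and ciliated cell genes in 2 of 5 (4; adjusted p = 0.296). Myl1 stood at 1211 ± 1016 in the libraries labelled mTEC2 and at 7.78 to 17.5 in the 4 labelled mTEC1 and mTEC4. Acta1 stood at 700 ± 207 against 0 to 14.1, and Trpm5 at 478 ± 37.7 against 0 to 29.8. The falls of these 3 genes therefore mainly mirror the high libraries labelled mTEC2 rather than a trait of mTEC4. Pan-epithelial genes fell in 5 of 10 (6 lower and 1 higher adjusted over the list alone; adjusted p = 0.296 with an estimated correlation), such as Cldn7 (log2 -2.66), Cldn3 (-2.31) and Krt19 (-1.43). The small GTPase Rab25 fell by 5.76 log2 units, Fezf2 by 2.47 and Aire by 2.47, to 29.0 ± 6.59 from 280 ± 255 (adjusted p = 0.0131). Among the genes that rose were the growth factor Pdgfd, absent from the other day 6 libraries and at least 10.3-fold higher, Pomc (3.60), Gzmc (4.99), Reg3b (4.36) and Il7 (2.85). Foxn1 (300 ± 68.4 against 247 ± 206, adjusted p = 0.135), Psmb11 (log2 0.79), Prss16 (0.60), Krt10 (0.66) and Dclk1 (-0.26) did not pass.

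Markers of non-epithelial cells moved with this label as well. Plvap, from the endothelial list (1 of 8 higher, 2 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation), stood at 427 ± 107 against 167 ± 207. The endothelial list averaged 1.86 log2 units for this label, 1.89 for day 6 mTEC2 and -3.75 for day 6 mTEC1, each against the others. Its rise therefore reflects the low libraries labelled day 6 mTEC1 rather than a trait of mTEC4. The collagen Col1a1, from the mesenchymal list (1 of 9, 3 adjusted over the list alone; adjusted p = 0.296 with an estimated correlation), was at 124 ± 17.2 against 24.2 ± 3.57. Camera also placed up the cTEC, dissociation stress and myeloid lists and down the tissue-restricted antigens. Il7 was the only member of these 4 lists called over all genes, 4 of 13, 0 of 12, 1 of 8 and 4 of 11 passed when adjusted over the list alone, and with an estimated correlation none held (adjusted p = 0.367 for myeloid genes, the lowest). There were 52 higher and 268 lower genes by limma, against 67 and 84 by edgeR, 110 and 152 by DESeq2 and 6 in all in the day 6 libraries alone. The count was 152 without library 2 labelled day 6 mTEC4, 72 and 103 without library 1 or 2 labelled day 6 mTEC1, and 1623 and 989 without library 1 or 2 labelled day 6 mTEC2. Of the 15 called genes named here, Trpm5, Cldn7, Rab25, Fezf2 and Il7 kept the call without each of the 6 libraries.

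At 6 weeks each population label held libraries with different marker genes, and limma called no gene between labels. Trpm5 and Avil of tuft cells reached 1689 to 2026 and 2637 to 3393 CPM in the libraries labelled cTEC 196, mTEC2 195, mTEC3 195 and mTEC4 195, against at most 90.2 and 223 in each of the other 16. Aire (1998 to 2486) and Fezf2 (1077 to 1497) were highest in the libraries labelled cTEC 191, mTEC1 191, mTEC2 191 and mTEC4 189, with next values of 216 and 464. The cortical genes Psmb11 (115 to 238, next 11.7), Prss16 (3453 to 7678, next 469), Ccl25 (2925 to 4012, next 991) and Cxcl12 (1538 to 2686, next 294) were highest in the 4 libraries labelled mTEC1 to mTEC4 with the number 196. Krt5 (3468 to 3883, next 1537) and Krt14 (2161 to 2461, next 882) were highest in cTEC, mTEC1, mTEC2 and mTEC3 of number 189. Pth, parathyroid hormone (3891 to 13890, next 23; chromosome 7, 113385580 to 113388570, minus strand), and Chga, chromogranin A (4774 to 9630, next 174), were highest in cTEC 195, mTEC1 195, mTEC3 191 and mTEC4 191. The libraries are therefore named here by their labels, and no direction between 6-week labels is drawn.

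By limma 0 of 13610 genes passed for each label against the others. The counts at an unadjusted p below 0.05 were 153 for cTEC, 322 for mTEC1, 38 for mTEC2, 261 for mTEC3 and 147 for mTEC4, and edgeR called 0 in each and DESeq2 0 except for 1 gene for mTEC4. With simulated 8-fold changes in 100 genes, between 56 and 65 were recovered in these fits. The simulation shifted all libraries of a label together, whereas each real label held libraries with different marker genes. This recovery therefore does not tell whether differences between the cell populations would have been called. Camera placed cTEC genes and Foxn1 targets down in the libraries labelled cTEC (adjusted p = 0.00446 and adjusted p = 0.00555, and adjusted p = 0.938 for both with an estimated correlation). It placed tuft genes down in those labelled mTEC1 (adjusted p = 0.991 with an estimated correlation). In those labelled mTEC2, muscle genes were placed up and neuroendocrine, thymocyte, myeloid, mesenchymal and endothelial genes down, the lowest at adjusted p = 0.880 with an estimated correlation. In those labelled mTEC4 the Ccl21a and Pdpn list was placed down and endothelium up (adjusted p = 0.982 with an estimated correlation for both). No member of these lists was called, over all genes or adjusted over the list alone.

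**Figure D4:**
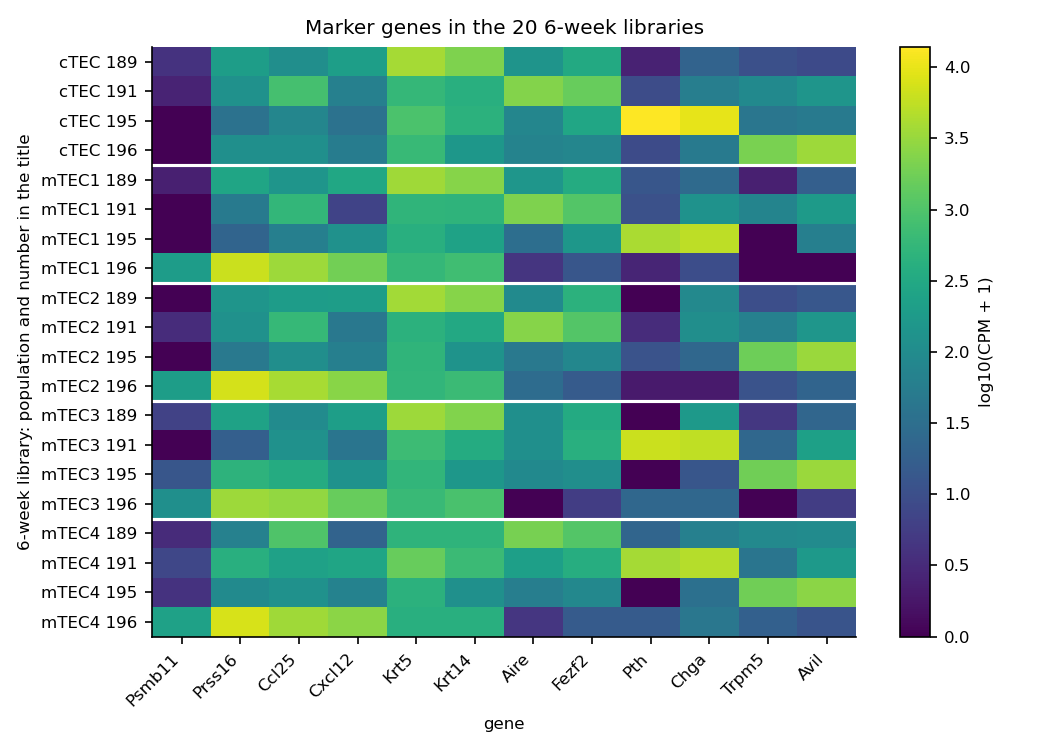
Levels of 12 marker genes as log10(CPM + 1) in the 20 TEC libraries at 6 weeks, 1 row per library, sorted by the population and number in the title. Psmb11 lies between 115 and 238 CPM in the 4 mTEC libraries of number 196 and is at most 11.7 in the other 16.

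Few genes were called between day 6 and 6 weeks within a label by limma, and how many depended on the tool. At 6 weeks the libraries of each of these labels differed in their highest population list. Age within 1 population was therefore not compared, and this mixture adds to the spread. Age and any library batch cannot be told apart either, as each age was collected on its own. The same holds for E17 against E15 and for 6-week cTEC against embryonic TEC. In the libraries labelled mTEC1, Fxyd3, a regulator of the sodium pump, was the only call, at 375 ± 33.1 CPM (n = 4) against 45.8 ± 12.7 (n = 2; adjusted p = 0.00175). In those labelled mTEC2, the heat shock gene Hspa1a was higher at 6 weeks (1346 ± 618 against 135 ± 42.3, adjusted p = 0.0414) and the muscle troponin Tnnc2 lower (3.87 ± 6.17 against 298 ± 96.2, adjusted p = 0.0403). In those labelled mTEC4, the desmosomal gene Pkp1 (122 ± 37.0 against 4.33 ± 1.20), Urah (4.05 log2 units) and Hspa1a (2.46) rose. Cd14, with no UMI at day 6, was at least 8.08-fold higher, and the imprinted gene Mest (-6.10), Cthrc1 (-5.32), Stmn1 (-2.90) and Mzb1 (-4.24) were lower. Foxn1 did not pass in any of the 3 (log2 -2.35, 0.46 and -1.93). In all 3 labels camera placed cell cycle and thymocyte genes down and dissociation stress genes up. Adjusted over the list alone, 0 of 13 cell cycle genes passed in each label, 4, 2 and 2 of 13 thymocyte genes were lower and 9, 4 and 5 of 12 stress genes higher. Camera called 8, 12 and 12 lists in the 3 labels and 0 with an estimated correlation, the lowest being adjusted p = 0.208 for stress in mTEC1 and adjusted p = 0.134 for endothelium in mTEC2.

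Limma called 1, 2 and 45 of 13539 genes in the labels mTEC1, mTEC2 and mTEC4, the last as 30 higher and 15 lower, with 834, 1418 and 1791 at an unadjusted p below 0.05. DESeq2 called 90, 136 and 395, and edgeR 1, 0 and 6 (2 higher and 4 lower in mTEC4). Of 100 genes simulated with 8-fold changes these limma fits recovered 19, 37 and 36, so few calls do not show few differences. The median log2 change over all genes was -0.10, 0.19 and 0.18 by limma and 0.14, 0.32 and 0.33 by edgeR. Whether the differences between labels changed with age was tested by an interaction, which called 0 genes by limma, edgeR and DESeq2, with 628 at an unadjusted p below 0.05. Of 100 genes simulated with 8-fold changes the limma interaction recovered 0, so its 0 calls do not show that the differences stayed the same. It called 81 without library 1 and 1 without library 2 labelled day 6 mTEC2. For mTEC1 the call was lost without library 2 at day 6, and the count was 2 without day 6 library 1, 3 without 6-week 189 and 2 without 6-week 191. For mTEC2 it was 348 without day 6 library 1, 1 without day 6 library 2 and 0 without 6-week 189, 191 or 196. For mTEC4 it was 16 and 2 without day 6 library 1 or 2, and 21, 15, 3 and 98 without 6-week 189, 191, 195 or 196. Hspa1a and Tnnc2 were called in mTEC2 only without 6-week 195 or day 6 library 1, and Pkp1 was the 1 of 8 called genes named for mTEC4 that was called without each library. The 6-week and day 6 labels enter each of these comparisons.

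The libraries labelled 6-week cTEC had fewer cortical and cell cycle transcripts than embryonic TEC, and more keratinocyte, tuft and microfold ones. The cTEC list was the highest of the 5 population lists in 0 of these 4 libraries, so the direction is that of the label alone. Psmb11 stood at 1.17 ± 1.46 CPM against 265 ± 48.1 (log2 -6.63 ± 0.47, adjusted p = 0.000271, n = 4 and 4). Prss16 (chromosome 13, 22002173 to 22009742, minus strand) stood at 120 ± 68.3 against 5021 ± 739, and Foxn1 at 118 ± 137 against 810 ± 221 (adjusted p = 0.0137 by limma). Of 13 cTEC genes 9 fell with 0 higher (11 adjusted over the list alone; adjusted p = 0.286 with an estimated correlation), such as Ly75 (-3.33) and Cxcl12 (-3.56), and of 9 Foxn1 targets 8 (8; adjusted p = 0.286). Organogenesis factors fell in 3 of 7 (5; adjusted p = 0.383), and Pax1 was at 87.4 ± 64.4 against 1252 ± 182. Cell cycle genes fell in 9 of 13 (12; adjusted p = 0.329), with Birc5 at 8.14 ± 7.94 against 135 ± 47.9, Ube2c at a log2 change of -3.72 and Top2a at -2.19. Fn1, fibronectin, was at 34.2 ± 56.2 against 1060 ± 272 and Frem2, a basement membrane protein, at 1.17 ± 1.46 against 192 ± 29.2. By contrast, the 4 libraries at 6 weeks labelled mTEC1 to mTEC4 of number 196 held Psmb11 at 115 to 238 CPM and Prss16 at 3453 to 7678. This comparison of labels therefore does not show a loss of cortical transcripts with age.

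Cornified keratinocyte genes rose in 9 of 15 in the same comparison (13 adjusted over the list alone; adjusted p = 0.383 with an estimated correlation), with Sprr1a up by 6.59, at 150 to 5972 CPM among the 4 libraries. Tuft genes rose in 8 of 19 (13 adjusted over the list alone; adjusted p = 0.383 with an estimated correlation), with Dclk1 (chromosome 3, 55242364 to 55539068, plus strand) at 32.3 ± 11.9 against 2.0 ± 0.901. Microfold genes rose in 6 of 7 (6; adjusted p = 0.286), among them the transcytosis receptor Gp2 (178 ± 102 against 0.442 ± 0.884), the chemokine Ccl20 (6.48) and Spib (3.31), and dissociation stress genes in 9 of 12 (9; adjusted p = 0.306). Cyp2a5, a cytochrome P450, was at 434 ± 209 against 1.68 ± 0.956. Pan-epithelial genes rose in 6 of 10 and fell in 1 (7 and 2 adjusted over the list alone; adjusted p = 0.329 with an estimated correlation). Markers of other cells were placed up with them: 2 of 7 myeloid and 2 of 6 endothelial genes rose (3 and 2 adjusted over the list alone; adjusted p = 0.404 and adjusted p = 0.394 with an estimated correlation). Camera also placed up neuroendocrine, ciliated and tissue-restricted antigen genes (1 of 6, 1 of 3 and 2 of 10 higher; 4, 3 and 2 adjusted over the list alone) and down the Notch and Wnt list (1 higher and 2 lower of 12, the same adjusted over the list alone). With an estimated correlation these 4 were at adjusted p = 0.383 to adjusted p = 0.520. Krt10 (adjusted p = 0.0536, called by edgeR and DESeq2) and Aire (adjusted p = 0.635) did not pass by limma. Limma called 1074 genes higher and 710 lower of 11199, DESeq2 3244 in all, and the 20 TEC libraries at 6 weeks taken as 1 group, a comparison added after the data were seen, 1093 higher and 895 lower with 1307 shared. The count fell to 535 or 591 without E15 library 1 or 2 and to 516 or 556 without E17 library 1 or 2. Top2a lost its call without each of these, Foxn1 without each but E17 library 2, and Cxcl12 and Spib with the 20 libraries as 1 group.

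Gapdh, often used as a reference transcript, fell into separate ranges across the series. It lay between 0 and 29.7 CPM in 20 libraries and between 532 and 1530 in the other 13. The low values comprised both E17 libraries, 17 of the 20 TEC libraries at 6 weeks and HFC library 2 (21.8, against 833 and 786 in HFC libraries 1 and 3).

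**Figure D5:**
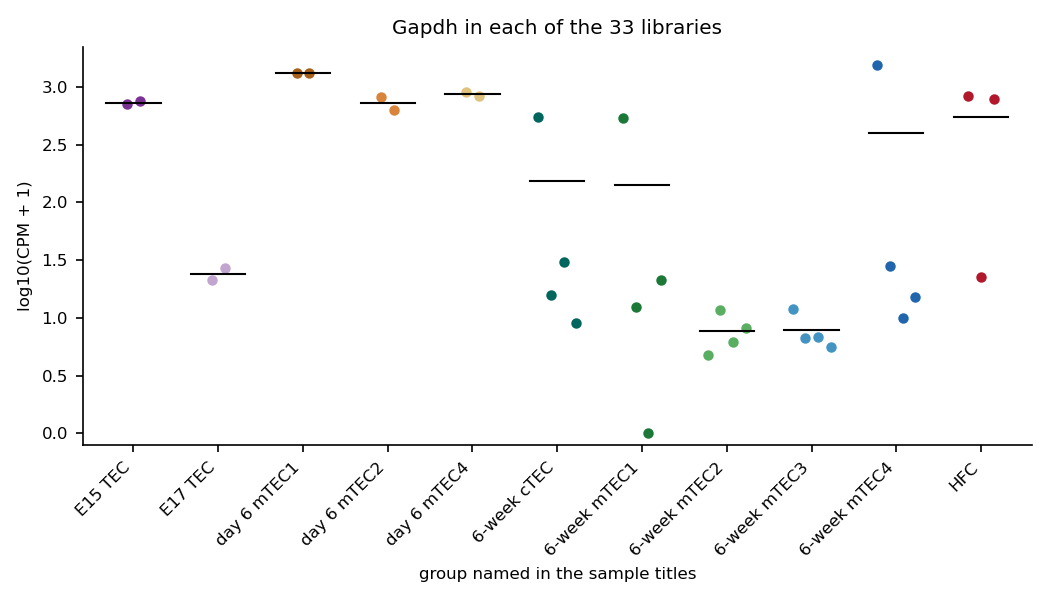
Gapdh in each of the 33 libraries as log10(CPM + 1), by the group in the sample titles; points are libraries and bars are group mean CPM on that axis. 20 libraries lie at or below 29.7 CPM and 13 at or above 532.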

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

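The tests of explanations in this part were chosen after the results were seen.

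At 6 weeks single libraries stood far from the others of their label. In 5 labels of 4 libraries and for 7 measures, the gap between the highest or lowest library and the next was divided by the range of the 4 and set against Dixon's critical value. This was exceeded in 14 of 35 checks, against 1.75 expected at about 1 in 20 for independent, normally distributed values. Gene levels entered as CPM without a log, and Psmb11 and Prss16 flagged the same libraries. The 1.75 is therefore no chance rate for these data. Psmb11 stood at 192, 203, 115 and 238 CPM in number 196 of the labels mTEC1, mTEC2, mTEC3 and mTEC4, while the other 3 libraries of each label had at most 1.31, 2.38, 11.7 and 6.74. Prss16 stood at 6477, 7642, 3453 and 7678 in the same libraries, with at most 268, 143, 469 and 405 in the others. Aire stood at 2405, 2156 and 2486 in number 191 of the labels cTEC, mTEC1 and mTEC2 and at 1998 in mTEC4 189, with at most 136, 148, 95.3 and 216 in the others of these labels. Krt10 stood at 1652 in mTEC1 195 and 1531 in mTEC4 191, with at most 311 and 254 in the others.

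The 6-week libraries did not fall together by the population in their titles: the library with the highest correlation carried the same population in 0 of 20 cases and the same number in 13. A candidate explanation is that titles were given to the columns in another order than the libraries. Correlations averaged 0.8654 within runs of 4 neighbouring columns, 0.7861 within numbers and 0.6905 within titles. The highest of the 5 population marker lists was the one of the title in 4 of 20 libraries, against 4 by chance (permutation p = 0.5855). Each of the 5 lists was highest in 4 libraries, and these 4 stood in the same run of neighbouring columns. In column order the runs carried the lists of mTEC1, mTEC2, mTEC3, mTEC4 and cTEC. These lists had been drawn before the data were examined. These values go with the explanation. It stays open, because the runs were noticed in marker levels of the same libraries and no other measurement links columns to cells. Differences between the numbers in the titles, whether animals, sorts or days, are argued against as the whole cause, since 7 libraries were closest to one with another number, and pairs of 1 number averaged 0.687 in different runs of 4 (20 pairs) while pairs of different numbers averaged 0.827 within a run (10 pairs). No library was assigned to another population here, and how populations differ at 6 weeks stays open.

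The number of genes called was also counted in 100 groupings of the same libraries. For each 6-week label against the others 0 genes were called, a number that 100 of 100 groupings must reach, so for these labels the groupings say nothing about chance. In the labels cTEC, mTEC1, mTEC2, mTEC3 and mTEC4, 3, 4, 4, 6 and 4 of the other groupings called any gene, with a median of 0 and highest counts of 474, 245, 1320, 367 and 1622. Whether the few groupings with many calls follow another structure of the samples was not tested, so they do not show one. For HFC against TEC the real count of 2886 was reached by 1 of 100 groupings, itself, with 819 the highest other. This share is the smallest that 100 groupings allow, and it argues against an accidental grouping of these libraries. For the libraries labelled 6-week cTEC against embryonic TEC the real count of 1784 was reached by 3 of 100, with 2539 the highest other. The 2 others parted the libraries into the same 4 and 4, and groupings that parted them otherwise called 0 genes. The count thus goes with this parting of the libraries. Both tests take the libraries as exchangeable, and the labels do not say whether they came from separate animals. Chance is therefore not excluded beyond these shares.

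Gapdh was between 0 and 29.7 CPM in 20 libraries and at least 532 in the other 13, also within HFC. Lower glycolysis is argued against: between E15 and E17, where Gapdh fell from 730 to 23.1, the median log2 change of 10 other glycolytic enzymes was 0.54. Lower depth is argued against as well, since the deepest of the 20 libraries held 1131294 UMIs and the HFC libraries, among them 2 of the other 13, at most 679168. That Gapdh reads were handled differently in some libraries may be an explanation, as 0 other genes parted the same libraries by 4-fold or more, but the steps before the deposited values were not analysed here, so this cannot be told apart from a change in Gapdh alone.

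Endothelial genes were low in the libraries labelled day 6 mTEC1, at a mean log2 change of -3.75 over 8 markers against the other day 6 libraries. A higher share of epithelial cells, with all other cells lowered alike, is argued against, because thymocyte markers averaged 0.23, although myeloid (-0.27), mesenchymal (-0.60) and B cell markers (-1.41, 2 genes) were lower. Fewer endothelial cells and less RNA from each of them in the sort both remain possible explanations of the -3.75 and cannot be told apart, since neither cell number nor RNA per cell was measured. A difference between the populations named in the titles also stays open, untested.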

How the results depend on the processing

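Fits of the compared groups alone and of the 20 TEC libraries at 6 weeks as 1 group were chosen after the data were seen, and the other settings before. Counts of called genes are given here where they moved by more than 1.5 times, against 2886 for HFC, 88 for E17, 361, 905 and 320 for the day 6 labels mTEC1, mTEC2 and mTEC4, 1, 2 and 45 for age within these labels, 0 for the interaction and for each 6-week label, and 1784 for the libraries labelled 6-week cTEC against embryonic TEC. The cause was not tested unless given. With edgeR the count was 167 for E17, 151 for day 6 mTEC4, and 0 and 6 for age in mTEC2 and mTEC4. With DESeq2 it was 247 for E17, 90, 136 and 395 for age, 3244 for cTEC against embryonic TEC and 1 for 6-week mTEC4. With a pseudocount of 0.5 age in mTEC2 had 0, and with 5 it had 56, age in mTEC4 97 and the interaction 2. A filter at a mean of 10 gave 190 for day 6 mTEC4 and 11, 0 and 69 for age. Median of ratios scaling gave 2 and robust moderation 3 for age in mTEC1. In fits of the compared groups alone E17 had 505 and the day 6 labels 24, 163 and 6. Of 350 tests of gene lists camera called 114 at the preset correlation and 5 with an estimated one, and fry called 61. Leaving out 1 library at a time gave 1547 to 3381 genes for HFC, 5 to 16 for E17, 0 to 1745, 487 to 2687 and 72 to 1623 for the day 6 labels, 0 to 3, 0 to 348 and 2 to 98 for age, 0 to 81 for the interaction, 516 to 2357 for cTEC against embryonic TEC and 0 throughout for the 6-week labels. Where a group of 2 lost a library, the lone library was assumed to vary like the other groups. Settings were tallied over the genes named for a comparison, leaving out those in which the filter or DESeq2 gave no adjusted p. The call stayed as it was in 2690, ended in 297 and was added in 9. In 1 the direction reversed for a gene called in either fit. Genes called in neither fit count among the 2690, even where their direction changed. The reversal was that of Krt10 in day 6 mTEC2. It ran from -1.61 to 1.39 on the log2 scale when a library of that label was left out. The numbers in the titles were not taken to pair the libraries, as same-numbered pairs did not all correlate above 0.1. At 6 weeks correlations of same-numbered deviations had a median of 0.236 over 40 pairs, 24 of them above 0.1, and 11 of 20 libraries were closest to their own number. At day 6 they lay between -0.00122 and 0.0395 in 6 pairs, with 6 of 6 libraries closest to their own number, and the embryonic value was 0.00910. In groups of 2 libraries the deviations mirror each other, so each value occurs for both numbers. The closest number then follows from the sign of these small values and says little. A block on the number gave 205 genes for day 6 mTEC4 and moved no other count of genes by over 1.5 times. In the comparisons that allow it, the block took the lists called by camera from 54 to 66, with 8 in place of 2 for 6-week cTEC and 2 in place of 0 for 6-week mTEC3. Depth limits low genes: 3 UMIs, the limit that a count of 0 allows, are 30.4 CPM in the shallowest library and 1.73 in the deepest. Rescaling to the same total was not run, because the values already share it.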

Other observations

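The genes of this part were chosen after their values were seen, and they come from the same limma fits, with no further test. Further single genes differed between HFC and 6-week TEC. Apoe, apolipoprotein E, was the most abundant transcript of each HFC library, with between 6.20% and 9.90% of its UMIs, and lay 5.55 log2 units above TEC (limma adjusted p = 7.07e-05). Lgals7, galectin-7 of stratified epithelia, stood at 21920 ± 4675 CPM in HFC, 9.13 log2 units above TEC. Krt79, a keratin of the upper hair follicle, stood at 4735 ± 2095 (n = 3) against 68.5 ± 64.5 (n = 20), and Hr, the hairless corepressor, at 796 ± 176 against 12.1 ± 17.2. The chemokine Cxcl14 (6.25 log2 units) and the peptidase Klk10 (6.69) rose as well. Within the Notch and Wnt list, which camera did not place apart, the receptors Notch1 (1.87) and Notch3 (2.51) were called higher, Notch1 not without any 1 of the 3 HFC libraries and Notch3 not without library 3, while the ligand Dll4 and the target Hey1 had no UMI in HFC and were at least 33.8-fold and 30.7-fold lower.

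Dll4, the ligand that directs thymic progenitors to the T lineage, was also lower in the libraries labelled 6-week cTEC than in embryonic TEC, at 30.8 ± 42.1 CPM against 334 ± 89.5 (log2 -4.21, limma adjusted p = 0.00683, n = 4 and 4). The cTEC list was the highest population list in 0 of these 4 libraries labelled cTEC. The 4 highest 6-week libraries, labelled mTEC1 to mTEC4, held Dll4 at 138 to 227 CPM. The immediate early genes Fosb (2.84), Dusp1 (2.79) and Junb (1.92) were higher in the libraries labelled 6-week cTEC than in embryonic TEC. They belong to the dissociation stress list, which lost its call in this comparison with an estimated correlation. At 6 weeks further tuft cell genes shared the 4 libraries with the highest Trpm5: the cytokine Il25 stood at 759 to 1101 CPM against at most 34.3 in the other 16, and Alox5, which makes leukotrienes, at 868 to 1256 against at most 81.1. The cornified envelope gene Sprr1a (4160 to 6050, next 1521) and Sbsn (2090 to 3819, next 874) were highest in the 4 libraries with the highest Pth and Chga, cTEC 195, mTEC1 195, mTEC3 191 and mTEC4 191. Which cells within a library carry these transcripts cannot be read from bulk RNA.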
